A study of Mus musculus with 30 samples.

How the data were processed

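Preputial glands, paired modified sebaceous glands beside the penis of the male mouse, were dissected, per the labels' protocols, from male mice fed benzo[a]pyrene (BaP), a carcinogenic polycyclic aromatic hydrocarbon from combustion. Per the labels' protocols the diet began at 6 weeks of age and gave about 12.5 mg/kg/day. The labels name the tissue preputial gland duct. The genotypes were wild type (WT), Cyp1a1 knockout (KO) and Cyp1a1/1b1 double knockout (DKO), and glands were taken at weeks 0, 4, 8, 12 and 16. Per the labels' protocols, RNA was extracted from thawed frozen glands with Tri-Reagent and RNeasy columns, amplified with the Ovation Pico WTA kit and labelled with biotin. The 30 arrays fell into 15 groups of 2 mice each. RMA, named without a version in the submitters' processing notes, is a background correction, quantile normalization and probe summary for arrays. The annotation build behind the probe sets was not given in the sources used here. The deposited values are log2 intensities per probe set, and they were used on that log2 scale as the authors left them. Their number of arrays, 2 per group, limits the precision.

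Of 21212 probe sets, 18786 carried 1 gene symbol, 6 carried several and 2420 were not listed in the platform table. The probe set with the highest mean over all arrays stood for each gene, which gave 18784 genes. No low-value filter was applied. Across the 30 arrays no 2 held identical values.

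Groups, comparisons, gene lists and alternatives were fixed before the data were examined, except where stated. A single linear model with a mean for each of the 15 groups was fitted in limma 3.58.1 under R 4.3.3, with moderated variances (residual degrees of freedom 15, prior degrees of freedom 6.91). The 15 comparisons were, within each genotype, the mean of weeks 4 to 16 against week 0 and week 16 against week 0; between genotypes, the mean over the 5 weeks and week 16 alone; and the differences between genotypes in the change from week 0 to week 16. Single weeks against week 0, genotypes within single weeks and a moderated F test over the weeks of each genotype were secondary. All tests were two-sided, and p values were adjusted over all genes by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05. Errors after ± are standard errors of the model unless SD is written. The model gives each gene a single spread shared by all groups. Array weights, which are larger where arrays vary less, were 1.44 to 6.39 in WT and 0.178 to 0.350 in DKO. The errors and p values are therefore likely too large for changes within WT and too small for changes within DKO. Mice killed at week 0 were the only animals without BaP, so exposure and age rose together.

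The 19 gene lists covered targets of the aryl hydrocarbon receptor (AhR), glutathione and NRF2 genes, p53 and DNA damage, the cell cycle, basal and activated keratinocytes, cornified-layer genes, sebaceous lipid genes, neutrophils and acute inflammation, macrophages, lymphocytes, stroma, invasion proteases, hypoxia and glycolysis, and interferon. The others marked skeletal muscle, fat cells, endothelium, red cells and male accessory glands. They came from textbook knowledge, and 250 of their 278 genes were measured. Each list was tested with camera, limma's competitive set test, at a preset correlation of 0.01 between genes and again with the correlation estimated from the data. Camera p values were adjusted over the 19 lists within a comparison. Only the cornified-layer, AhR and neutrophil lists in the DKO change over weeks 4 to 16 passed the threshold with the estimated correlation. "Adjusted over the list alone" gives the count of members past 0.05 when only that list's genes enter the adjustment.

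The rule for naming genes took Cyp1a1 and Cyp1b1, the 10 highest and 10 lowest called changes of each comparison whose arrays did not overlap, without predicted gene models, and up to 4 members of each list with the smallest adjusted p. The text names a part of these, picked after their values were seen, so the share of named genes that held under other settings says little about the rest. Tnfaip6, Ccl7 and Pon1, and the 5 genes called between Cyp1a1 KO and WT at week 12, were named outside the rule after their values were seen, because so few were called.

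The other settings tried were quantile normalization of the deposited values, centring each array on its median, a filter on low values, a variance model with a trend and robust estimates, array weights, a fit with only the groups compared, the replicate number of the labels as a block, the mean of all probe sets of a gene, and leaving out each array in turn. Further settings were chosen after seeing the data. They treated the number in each array's label description, 1 to 20 or 22 to 33, as a block, ran the fit within each range of numbers, and left out 9 arrays with a narrow range of values (a standard deviation of all log2 values under 1.5). The meaning of the label numbers is not stated. In 100 random splits with seed 1, labels of 2 genotypes were exchanged within weeks. The pipeline was tested on simulated data with 200 changed genes of known size. The simulated arrays had the same spread for a gene in every group, independent genes and no difference in range of values. The recovery in the real arrays may therefore differ. In the WT weeks 4 to 16 comparison it recovered 26.9% of genes with a true log2 change of 1, 86.6% of those with 2 and 100% of those with 4. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.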

Results

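Expression was measured on 30 arrays in tissue that the labels name preputial gland duct and whose protocols describe as dissected preputial glands, with 2 mice in each of 15 groups formed by 3 genotypes and 5 durations of oral BaP. The questions set by the design were how the genotypes differ and how each changes with exposure, in a study of squamous cell carcinoma forming in the duct. The arrays differed in their range of values. In 21 arrays the standard deviation of all log2 values lay between 1.70 and 2.08, and in 9 it lay between 1.15 and 1.42. These 9 low-range arrays were 8 of the 10 arrays labelled DKO and 1 Cyp1a1 KO array, replicate 2 of week 12. Only DKO week 0 replicate 1 and DKO week 12 replicate 2 had the normal range. Correlations across genes, which are not independent replicates, had a median of 0.975 between normal-range arrays and 0.797 between low-range and normal-range arrays. Where both arrays of a group were low-range, they correlated at 0.803 (DKO week 4), 0.817 (DKO week 8) and 0.711 (DKO week 16). The low-range arrays therefore also differed among themselves, which a single offset does not remove. Array and RNA quality were not tested. The label numbers were 1 to 10 for WT, 11 to 19 and 30 for Cyp1a1 KO, and 20, 22 to 28, 31 and 33 for DKO. Genotype and number range were therefore nearly the same split. Results of a fit with the number range as a block, and of fits within a range, are given with the DKO comparisons. The block offset rests on the 2 groups that hold both number ranges, Cyp1a1 KO week 12 and DKO week 0. Errors between the arrays labelled DKO and the other genotypes were therefore larger with it (S100a8 between DKO and WT, SE 0.85 against 0.40). A call lost with the block does not by itself show a smaller difference. In some other comparisons the block raised the count of called genes, as given below.

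**Figure D1:**
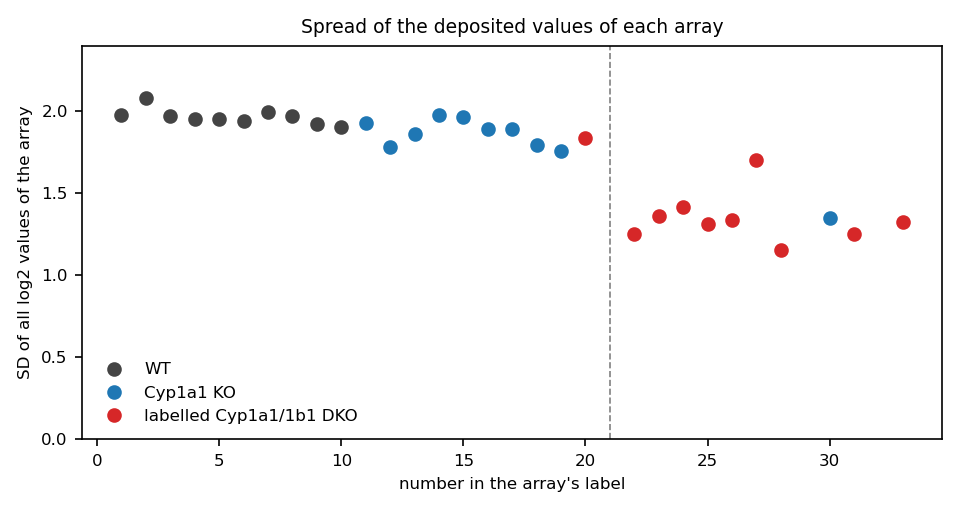
Standard deviation of all log2 values on each array (vertical axis, log2 units) by the number in its label (horizontal axis), coloured by genotype. The 9 arrays between 1.15 and 1.42 were 8 labelled DKO and 1 Cyp1a1 KO, and the other 21 lay between 1.70 and 2.08.

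Cyp1a1 and Cyp1b1 encode cytochrome P450 enzymes that oxidise BaP and are induced through AhR. Cyp1a1 signal was low in every group, with means from 4.36 to 4.54 in WT, 3.75 to 4.47 in Cyp1a1 KO and 4.25 to 5.39 in DKO. It therefore did not separate the genotypes. Cyp1b1 stayed between 6.29 and 6.64 in WT. In Cyp1a1 KO it was 6.67 ± 0.02 (SD, n = 2) at week 0 and 8.52, 8.53, 8.23 and 8.61 at weeks 4, 8, 12 and 16. In the arrays labelled DKO, where the gene was targeted, it was higher, at 8.11 ± 0.89 (SD, n = 2) before BaP and 10.39, 10.37, 10.27 and 9.94 afterwards. Cyp1b1 exceeded WT by 1.63 ± 0.17 log2 in Cyp1a1 KO (10 arrays each, adjusted p = 1.27e-05) and by 3.33 ± 0.17 in the arrays labelled DKO (adjusted p = 2.18e-11; 4.37 with the number block). The arrays labelled DKO exceeded Cyp1a1 KO by 1.70 ± 0.17 (adjusted p = 1.15e-06). That difference was 2.62 with the number block. Within numbers 1 to 20 it can be had at week 0 only, from 1 DKO array assumed to vary like the other groups (2.06, adjusted p = 0.00272), and within numbers 22 to 33 at week 12 only (2.56, adjusted p = 0.373). Where the probe set lies relative to the deleted part of the gene was not used here, so the signal does not check the genotype.

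**Figure D2:**
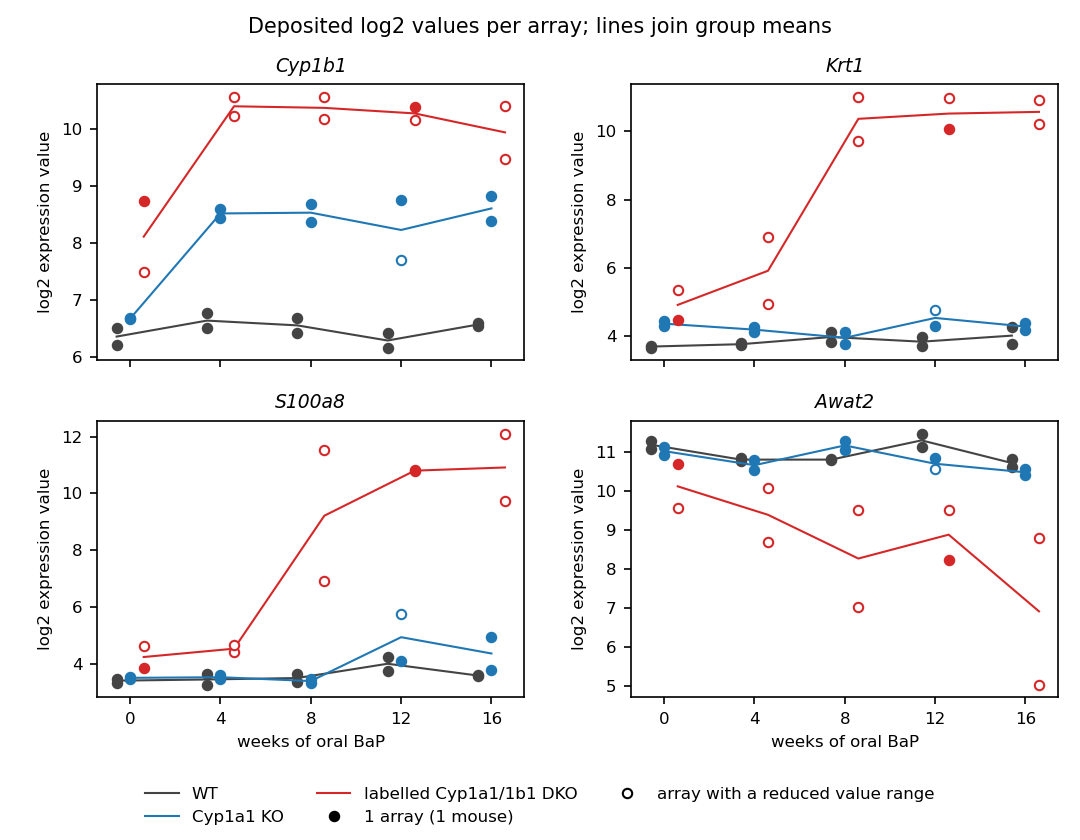
Log2 values of Cyp1b1, Krt1, S100a8 and Awat2 (vertical axes) at weeks 0 to 16 of BaP (horizontal axis). Each point is an array, open where the array had the low range, and lines join the means of the 2 arrays per group. In DKO, mean Krt1 went from 4.92 to 10.57 and mean Awat2 from 10.12 to 6.92 between weeks 0 and 16, with week 16 Awat2 arrays at 5.04 and 8.79.

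In WT glands no single gene was called over weeks 4 to 16 or at week 16 against week 0 by limma. At an unadjusted p under 0.05 there were 154 and 227 genes, where 939.2 would be expected by chance. The spread in this fit is shared with the more variable DKO arrays, so p values in WT are likely too large. The stroma list holds genes of collagens and other matrix proteins, and also contractile and other genes such as Acta2, Tagln, Vim and Pdgfrb. It lay higher over weeks 4 to 16 (median 0.30, 13 of 14 positive, camera adjusted p = 0.00504) and at week 16 (median 0.44, camera adjusted p = 0.000812). Cell cycle genes lay lower over weeks 4 to 16, with 27 of 30 negative (median -0.24, camera adjusted p = 0.000176). The neutrophil list (median 0.20, camera adjusted p = 0.0303) and the lymphocyte list (median 0.22, camera adjusted p = 0.0308) lay higher. None of these members was called, over all genes or adjusted over the list alone. After the correlation was estimated, the lists gave adjusted p = 0.473, and stroma at week 16 gave adjusted p = 0.629. Cyp1b1 differed by 0.15 ± 0.31 over weeks 4 to 16 (adjusted p = 1, 10 arrays).

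At week 12 alone, 2 genes were called in WT, and the F test over the weeks called the same 2 genes. Tnfaip6, a hyaluronan-binding protein induced by inflammation, rose by 3.14 ± 0.42 log2, 8.79-fold (adjusted p = 0.00352, 2 arrays against 2). Ccl7, a chemokine for monocytes, rose by 2.17 ± 0.34 (adjusted p = 0.0194). Both fell short with quantile normalization or with only the 2 groups in the fit. Without WT week 0 replicate 1, WT week 0 replicate 2 or WT week 12 replicate 2 no gene was called. Tnfaip6 then had adjusted p = 0.210, 0.0847 and 0.546, and Ccl7 had 0.895, 0.128 and 0.872, and also 0.0912 without WT week 12 replicate 1.

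In Cyp1a1 KO glands Cyp1b1 was 1.80 ± 0.31 log2 higher over weeks 4 to 16 than at week 0 and 1.93 ± 0.39 higher at week 16, but neither passed (adjusted p = 0.133 and 0.358). Without KO week 12 replicate 2, the low-range array, the change over weeks 4 to 16 was 1.93 and was called (adjusted p = 0.0230). It was also called with quantile normalization (adjusted p = 0.00286) and with the number block (1.94, adjusted p = 0.000550). AhR targets lay higher as a list over weeks 4 to 16 (median 0.40, 8 of 10 positive, camera adjusted p = 0.00201). None was called over all genes and 1 was adjusted over the list alone. Hypoxia and glycolysis genes (median 0.39, camera adjusted p = 0.00201), basal keratinocyte genes (median 0.17) and fat cell genes (median 0.32, both camera adjusted p = 0.0196) also lay higher, with no member called over all genes or adjusted over the list alone. At week 16 cornified-layer genes lay higher (median 0.31, 15 of 20 positive, camera adjusted p = 0.01003). Tested with an estimated correlation, these lists had adjusted p = 0.176, 0.458, 0.571, 0.571 and 0.903.

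No gene was called by limma in Cyp1a1 KO over weeks 4 to 16 or at week 16, with 258 and 217 genes at an unadjusted p under 0.05. Without KO week 12 replicate 2 the first count was 1, and quantile normalization and array weights each gave at least 1 gene in both comparisons. At week 4 alone Pon1, the secreted lipolactonase paraoxonase 1, rose by 2.89 ± 0.38 log2, 7.40-fold (adjusted p = 0.00238, 2 arrays against 2). It lost its call with quantile normalization and without KO week 0 replicate 1 (adjusted p = 0.102), KO week 0 replicate 2 (0.0892) or KO week 4 replicate 2 (0.358). Without these arrays no gene was called, and without KO week 4 replicate 1 the count was 2. The F test over weeks called 0 genes, with 499 at an unadjusted p under 0.05. In replicate 2 of week 4 the skeletal muscle gene Tnnt3 was at 8.58.

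In the arrays labelled DKO, genes of the cornified layer and of neutrophil inflammation rose during BaP feeding. Over weeks 4 to 16, Krt1 and Krt10, the keratin pair of differentiating epidermis, rose by 4.43 ± 0.39 and 2.87 ± 0.31 log2 (adjusted p = 8.05e-07 and 1.67e-05, 8 arrays against 2). Outside the lists Stfa1, a cysteine protease inhibitor of the stefin A family, rose by 6.33 ± 0.50 and Defb4, an antimicrobial beta-defensin, by 5.91 ± 0.47 (both adjusted p = 1.75e-07). Week 0 means of Krt1 (4.92), Stfa1 (4.64), S100a8 (4.23) and Defb4 (3.80) lay below the median of every array (5.12 to 5.47). No fold is given for these genes and Saa3, since background at such levels was not measured. Their log2 differences carry the same limit. The cornified-layer list had 6 of 20 members risen, none fallen and 14 not called, and 12 risen when adjusted over the list alone. All 20 were positive (median 1.14, camera adjusted p = 4.12e-15, and adjusted p = 0.00608 with an estimated correlation). Its members Sprr2d, a cornified envelope precursor, and Lce3a, a late envelope protein, rose by 4.09 ± 0.56 and 3.49 ± 0.73. Rptn, the envelope protein repetin, which is outside the list, rose by 3.75 ± 0.60. Of neutrophil and acute inflammation genes, 4 of 19 rose and 15 were not called, with 6 risen when adjusted over the list alone. All 19 were positive (median 0.67, camera adjusted p = 5.92e-07, and adjusted p = 0.0452 with an estimated correlation). S100a8, a calprotectin subunit abundant in neutrophils, rose by 4.63 ± 0.70 (adjusted p = 0.00200), and Cxcl2, a neutrophil chemokine, by 2.45 ± 0.51 (adjusted p = 0.0192). Outside that list Il1f9, an older symbol of an IL-36 cytokine, rose by 2.88 ± 0.53 (adjusted p = 0.0112). Stefin, Sprr and Lce genes have close relatives, so their probe sets may not be specific.

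AhR targets rose as a list in the same arrays (median 0.97, camera adjusted p = 8.65e-05, and adjusted p = 0.0394 with an estimated correlation). Of 10 members, 2 rose and 8 were not called, with 6 risen when adjusted over the list alone. Cyp1b1 rose by 2.13 ± 0.31 (adjusted p = 0.00110), and Nqo1, a quinone reductase, by 1.40 ± 0.33 (adjusted p = 0.0421). Nqo1 lost its call without DKO week 0 replicate 1 (adjusted p = 0.123) or DKO week 4 replicate 2 (0.0503) and with median centring (0.0646) and the replicate block (0.0514). Macrophage genes (median 0.53, camera adjusted p = 0.0104) and lymphocyte genes (median 0.59, camera adjusted p = 0.0349) lay higher with no member called. Adjusted over the list alone, 4 and 1 of these rose, and with an estimated correlation the lists had adjusted p = 0.439 and 0.294. Sebaceous lipid genes lay lower (median -0.74, camera adjusted p = 0.00124). None of their 19 members was called, over all genes or adjusted over the list alone, and the list had adjusted p = 0.264 with an estimated correlation. Awat2, a wax ester synthase, differed by -1.75 ± 0.63 (adjusted p = 0.171) and Plin2, a lipid droplet protein, by -1.45 ± 0.45 (adjusted p = 0.117). Awat2 was called without DKO week 16 replicate 2 (adjusted p = 0.0104), and Plin2 without that array (0.00985) or DKO week 8 replicate 1 (0.0278). Among other genes that fell, Tmem97, a sterol-regulated membrane protein, fell 5.29-fold (adjusted p = 0.000595). Wfdc18, a secreted protein with a whey acidic domain, fell by 2.32 ± 0.43 (adjusted p = 0.0112) and lost its call without DKO week 0 replicate 1 (0.145), as did Cxcl2 (0.172).

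In all, 183 genes were called over weeks 4 to 16 in DKO, 107 higher and 76 lower. Arrays of week 0 and later weeks did not overlap for 139 of the 183 and for 830 of all 18784 genes, and chance gives 4.44% of all genes. The number block gave 606 genes, 105 of them shared with the 183. With the block the cornified-layer (median 0.94), neutrophil (0.95), AhR (0.97) and macrophage (1.11) lists kept their calls, and the sebaceous (-0.28, adjusted p = 0.284) and lymphocyte (0.14, adjusted p = 0.554) lists did not. Of the genes named above as called, Cxcl2 lost its call with the block (2.05, adjusted p = 0.0501). Within numbers 22 to 33, where week 0 is 1 array, 12 genes were called. Stfa1 (7.13), Defb4 (5.27), Krt1 (3.98), Krt10 (3.32) and Rptn (4.99) were among them, while S100a8 (4.25, adjusted p = 0.397) and Cyp1b1 (2.76, adjusted p = 0.0958) were not. The 2 normal-range DKO arrays, 1 of week 12 against 1 of week 0, differed by 5.59 for Krt1, 6.98 for S100a8 and -2.44 for Awat2. With only the DKO groups in the fit 9 genes were called, among them Stfa1, Defb4, Krt1, Krt10, Sprr2d and Rptn, and with array weights 2 genes, Defb4 and Krt1. The count was 403 without DKO week 0 replicate 1, 1508 without week 0 replicate 2, 405 without week 8 replicate 1, 451 without week 12 replicate 2 and 706 without week 16 replicate 2. Against week 0, single weeks gave 98 genes at week 4, 179 at week 8 and 104 at week 12, and the F test over weeks called 748.

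At week 16 in DKO, Krt1 of the cornified-layer list rose by 5.65 ± 0.49 log2 (adjusted p = 8.96e-07, 2 arrays against 2) and S100a8 of the neutrophil list by 6.68 ± 0.89 (adjusted p = 0.000449). Outside the lists Stfa1 rose by 7.27 ± 0.64, Defb4 by 6.71 ± 0.60 (both adjusted p = 8.96e-07) and Saa3, an acute-phase serum amyloid, by 4.52 ± 0.60 (adjusted p = 0.000449). The 2 week 16 arrays had S100a8 at 12.11 and 9.72. Replicate 1 of week 16 had the narrowest range of all 30 arrays (SD 1.15). It also had the lowest median correlation with normal-range arrays (0.655). A gap between these 2 arrays can therefore not be read as a difference between mice alone. Krt10 rose by 3.35 ± 0.39, Sprr2d by 4.79 ± 0.71 and Cxcl2 by 4.17 ± 0.64, whereas Sprr4, another small proline-rich protein, fell by 4.36 ± 0.65 (adjusted p = 0.00139). The neutrophil list had 7 of 19 risen and none fallen, with 7 when adjusted over the list alone (median 1.05, camera adjusted p = 2.24e-06). The cornified-layer list had 5 of 20 risen, with 9 adjusted over the list alone (median 1.19, camera adjusted p = 3.03e-06). With an estimated correlation each had adjusted p = 0.107. Of 19 sebaceous genes, 2 fell, with 9 adjusted over the list alone (median -0.74, camera adjusted p = 0.000614, and adjusted p = 0.235 with an estimated correlation). These were Awat2 (-3.20 ± 0.79, adjusted p = 0.0284) and Plin2 (-2.19 ± 0.57, adjusted p = 0.0353).

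Other lists that shifted at week 16 in DKO were macrophage genes (2 of 13 risen, 3 adjusted over the list alone, median 0.82, camera adjusted p = 0.00726) and stroma genes (2 of 14 risen, 3 adjusted over the list alone, median 0.43, camera adjusted p = 0.0236). C1qc, a complement subunit made by macrophages, rose by 1.75 ± 0.46 (adjusted p = 0.0358), and Tnc, the matrix protein tenascin C, by 2.25 ± 0.50 (adjusted p = 0.0161). AhR targets had 2 of 10 risen and 3 adjusted over the list alone (median 0.62, camera adjusted p = 0.0130), namely Cyp1b1 (1.83 ± 0.39, adjusted p = 0.0138) and Ahrr, the AhR repressor (1.66 ± 0.38, adjusted p = 0.0199). Interferon genes had 1 of 10 risen and 3 adjusted over the list alone (median 0.65, camera adjusted p = 0.0130). Lymphocyte genes had none called and 1 adjusted over the list alone (median 0.55, camera adjusted p = 0.0463). After the correlation was estimated, the macrophage, stroma, AhR, interferon and lymphocyte lists had adjusted p = 0.435, 0.442, 0.197, 0.135 and 0.374. With the number block all but the lymphocyte list kept their calls, and the sebaceous list had adjusted p = 0.0476.

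At week 16 in DKO 759 genes were called, 384 higher and 375 lower, and the count was 534 with the number block. Left-out arrays moved the count to 282 without DKO week 0 replicate 1, 3393 without week 0 replicate 2, 194 without week 16 replicate 1 and 1960 without week 16 replicate 2. Without week 16 replicate 1 the calls of Awat2 (-1.32, adjusted p = 0.369), Plin2 (-0.98, 0.402), C1qc (0.190) and Tnc (0.111) were lost. Without week 0 replicate 1 those of Awat2 (0.159), Plin2 (0.158), Tnc (0.0965) and Ahrr (0.111) were lost. C1qc was lost without week 0 replicate 2 (0.147) and with median centring (0.0521), and Ahrr (0.0775) and Cyp1b1 (0.0549) without week 16 replicate 2. With the number block Awat2 (adjusted p = 0.0748), Plin2 (0.104) and Tnc (0.0521) were not called. Within numbers 22 to 33, 8 genes were called, including Stfa1 (8.06), Defb4 (6.08), Krt1 (5.20) and Krt10 (3.80). With only the DKO groups in the fit and with array weights 5 genes were called each, and Stfa1 was lost with the weights, while Krt1, Defb4 and S100a8 were called in both.

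Averaged over the 5 weeks, 6 of 19 sebaceous, 3 of 13 basal keratinocyte and 3 of 10 hypoxia and glycolysis genes were lower in Cyp1a1 KO glands than in WT. The 3 lists passed with the preset correlation only, and each had adjusted p = 0.272 with an estimated correlation. Stfa1 was higher by 3.28 ± 0.29 log2 (adjusted p = 1.15e-06, 10 arrays each) and Snap91, a clathrin assembly protein of synapses, was higher by 1.14 ± 0.16. The lower genes included Rpl29, a ribosomal protein (-2.58 ± 0.32), Aldh3b2, a lipid aldehyde dehydrogenase (-1.79 ± 0.26), and Cyb5r3, a cytochrome b5 reductase (-1.72 ± 0.15). Odc1, the rate-limiting enzyme of polyamine synthesis (-1.55 ± 0.22), and Hspa8, a constitutive heat shock chaperone (-1.48 ± 0.17), were lower too. In the sebaceous list 6 of 19 fell, with 7 adjusted over the list alone (median -0.30, camera adjusted p = 8.56e-05). Among them were Dgat2, which makes triglyceride (-1.14 ± 0.21), Mc5r, the melanocortin receptor of sebaceous cells (-1.11 ± 0.20), and Elovl3, a fatty acid elongase (-1.17 ± 0.23). In the basal keratinocyte list 3 of 13 fell, with 6 adjusted over the list alone (median -0.51, camera adjusted p = 8.56e-05), among them Krt5, the basal keratin (-0.81 ± 0.19), and Sfn, an epithelial 14-3-3 protein (-0.91 ± 0.17).

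Other lists lay lower in Cyp1a1 KO with the preset correlation. Hypoxia and glycolysis genes had 3 of 10 fallen, 3 adjusted over the list alone, including the glucose transporter Slc2a1 (-1.05 ± 0.20; list median -0.28, camera adjusted p = 0.000667). Glutathione and NRF2 genes had 2 of 16 fallen, 2 adjusted over the list alone (median -0.25, camera adjusted p = 0.00251), among them Gstp1, a glutathione transferase (-1.43 ± 0.27). Stroma genes had 3 of 14 fallen, 3 adjusted over the list alone, including smooth muscle actin Acta2 (-1.50 ± 0.33; list median -0.18, camera adjusted p = 0.0258). Cell cycle genes had 1 of 30 fallen, 2 adjusted over the list alone (median -0.22, camera adjusted p = 0.000667). Macrophage genes (median -0.21, camera adjusted p = 0.0250) had none called. Skeletal muscle genes lay higher, with all 13 positive and 1 risen adjusted over the list alone (median 0.30, camera adjusted p = 0.0122). Male accessory gland genes also lay higher, with all 7 positive (median 0.32, camera adjusted p = 0.0371). With an estimated correlation these 7 lists had adjusted p = 0.272, 0.318, 0.497, 0.473, 0.497, 0.491 and 0.491. Quantile normalization ended the calls of the glutathione (0.0697), stroma (0.0697), muscle (0.0697), cell cycle (0.169), macrophage (0.169) and accessory gland lists, and the basal, sebaceous and hypoxia lists kept theirs.

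The comparison called 813 genes, 72 higher and 741 lower. The arrays did not overlap for 199 of them and for 262 of all 18784 genes, where chance gives 0.00108%. That share, here and in the genotype comparisons below, holds only if any array could equally have carried either label. Quantile normalization left 128 genes, 28 higher and 100 lower. The calls of Sfn (adjusted p = 0.0868), Krt5 (0.0594), Dgat2 (0.0997), Elovl3 (0.0758), Slc2a1 (0.0737), Gstp1 (0.0736) and Acta2 (0.130) were then lost. Within numbers 1 to 20, which leaves out the low-range KO array and 9 DKO arrays that enter the spread, 4876 genes were called, 2610 higher and 2266 lower. The number block gave 988. From the lowest to the highest 25% of genes by level the median KO minus WT difference was 0.30, 0.15, -0.09 and -0.15, and without week 12 it was 0.21, 0.12, -0.07 and -0.05. This is the direction of the low-range arrays against their partners. The count was 508 without WT week 0 replicate 2, 500 and 540 without WT week 4 replicates 1 and 2, 525 and 522 without WT week 8 replicates 1 and 2, and 486 without WT week 16 replicate 2. It was 449 without KO week 0 replicate 1, 510 without KO week 4 replicate 1, 485 without KO week 8 replicate 2, 3248 without KO week 12 replicate 1 (1494 higher, 1754 lower) and 539 without KO week 12 replicate 2, the low-range array (51 higher, 488 lower). The WT and KO arrays also had separate label numbers, 1 to 10 and 11 to 19, so the order of the numbers and the genotype cannot be told apart.

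At week 16 alone 12 genes differed between Cyp1a1 KO and WT, 5 higher and 7 lower. Stfa1 was higher by 5.87 ± 0.64 log2 (adjusted p = 0.000106, 2 arrays each) and Stfa3, a related stefin, by 3.55 ± 0.41 (adjusted p = 0.000156). Mean Stfa1 in WT was 4.03, below the median of every array, where background was not measured. Csta1 (2.27 ± 0.38), another stefin, Cyp1b1 (2.03 ± 0.39) and Defb6, a beta-defensin (1.69 ± 0.32), were also higher. Cyb5r3 (-2.47 ± 0.34, adjusted p = 0.00178), Pmp22, a tetraspan membrane protein (-2.79 ± 0.47), Upk1b, a uroplakin (-2.57 ± 0.49), and Gins2, a subunit of the replicative helicase (-2.53 ± 0.44), were lower, as were Nprl2, Atp5d and Ppm1m. Without WT replicate 1, WT replicate 2 or KO replicate 1 of week 16 the count was 2, Stfa1 and Stfa3, and without KO replicate 2 it was 3. Cyb5r3 then had adjusted p = 0.0561, 0.0882 and 0.0906 without the first 3 of these arrays, and Cyp1b1 had 0.617, 0.802, 0.576 and 0.378 without each of the 4. Cyp1b1 also lost its call with median centring (0.104) and with the trend and robust variances (0.0989). Csta1, Defb6, Pmp22, Upk1b and Gins2 lost theirs without any 1 of the 4 arrays, with adjusted p from 0.154 to 0.948. Quantile normalization also ended the calls of Csta1 (0.263), Defb6 (0.157), Upk1b (0.214) and Gins2 (0.281), and the trend with robust variances that of Defb6 (0.125). With the replicate block 7 genes were called, without Cyp1b1, Defb6 and Upk1b (each 0.0603). Basal keratinocyte (median -0.92, camera adjusted p = 0.000168), stroma (-0.46, 0.000168), cell cycle (-0.30, 0.000264), sebaceous (-0.64, 0.000441), macrophage (-0.57, 0.000577) and glutathione genes (-0.40, 0.0133) lay lower as lists. No member was called over all genes, and 1 basal, 3 stroma and 1 glutathione gene fell when adjusted over the list alone. After the correlation was estimated, these lists had adjusted p from 0.446 to 0.477. The count was 64 with the number block, 2743 within numbers 1 to 20, 4592 with array weights and 3707 with only these groups in the fit. Within the other single weeks limma called 0 genes at weeks 0, 4 and 8, with 1292, 215 and 114 at an unadjusted p under 0.05, and 5 at week 12. These 5 were Tnfaip6, Ccl7, Cyb5r3, Ptges3l and Gstp3, and each was lower in KO.

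Between the arrays labelled DKO and WT, most cornified-layer and neutrophil genes measured were higher and most sebaceous genes lower, averaged over the 5 weeks. Of all 18784 genes 14011 were called, 8193 higher and 5818 lower. List counts here and in the next paragraph are to be read beside that share. The 3 lists passed with the preset correlation only, and each had adjusted p = 0.285 with an estimated correlation. Krt1 was higher by 4.60 ± 0.22 log2 (adjusted p = 1.24e-11, 10 arrays each; 3.99 with the number block, adjusted p = 7.31e-05), Krt10 was higher by 2.74 ± 0.17 (block 3.14) and Csta1 by 3.31 ± 0.17 (block 3.10). In the cornified-layer list 14 of 20 were higher, with 14 adjusted over the list alone, including Cnfn, the envelope protein cornifelin (2.06 ± 0.17, block 1.66; list median 1.19, camera adjusted p = 0.00102). In the neutrophil list 15 of 19 were higher and 2 lower, with the same counts adjusted over the list alone (median 0.90, camera adjusted p = 0.0226). S100a8 was higher by 4.36 ± 0.40 (block 3.27, adjusted p = 0.0692), and Cxcl2 was higher too (block 2.26 log2, adjusted p = 0.0794). No fold is given for Cxcl2, since its WT mean was 2.91 at week 0, a level at which background was not measured. In the sebaceous list 15 of 19 were lower and 2 higher, with 16 and 2 adjusted over the list alone (median -1.75, camera adjusted p = 3.48e-05). Outside the list Hilpda, a lipid droplet protein induced by hypoxia, differed by -3.46 ± 0.26 (block -1.45, adjusted p = 0.0253). Mc5r (-2.53 ± 0.20, block -1.17, adjusted p = 0.0736), fatty acid synthase Fasn (-2.17 ± 0.20, block -1.38, adjusted p = 0.111) and, outside the list, Insig1, a brake on sterol synthesis (-3.36 ± 0.32, block -1.78, adjusted p = 0.183), lost their calls with the block. At the preset correlation the 3 lists kept theirs with it (medians 1.12, 0.48 and -0.95).

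Further lists moved between these genotypes, and each lost its call with the number block. With all genes grouped by level over all arrays, the median DKO minus WT difference was 1.05 in the lowest group and -1.02 in the highest. Camera did not match genes on level. An effect of level was therefore not separated from the list shifts between DKO and WT, here and in the paragraph above. Cell cycle genes had 20 of 30 lower, 20 adjusted over the list alone (median -0.55, camera adjusted p = 0.000213; block median -0.05, adjusted p = 0.321), among them Foxm1, a mitotic transcription factor (-1.29 ± 0.16, block -1.14, adjusted p = 0.121), and Rrm2, a ribonucleotide reductase subunit (-1.32 ± 0.16, block -0.89, adjusted p = 0.237). Glutathione and NRF2 genes had 9 of 16 lower and 2 higher, the same adjusted over the list alone (median -0.91, camera adjusted p = 0.0194; block median -0.14, adjusted p = 0.617). Gclc, which makes the glutathione precursor, differed by -2.54 ± 0.30 (block -1.05, adjusted p = 0.434) and sulfiredoxin Srxn1 by -1.31 ± 0.15 (block -0.40, adjusted p = 0.523). Hypoxia genes had 6 of 10 lower, 6 adjusted over the list alone (median -0.78, camera adjusted p = 0.0194; block adjusted p = 0.701). Lymphocyte genes had 8 of 11 higher, 8 adjusted over the list alone (median 0.75, camera adjusted p = 0.0473; block adjusted p = 0.617). Male accessory gland genes had 7 of 7 higher, 7 adjusted over the list alone (median 1.43, camera adjusted p = 0.0159; block adjusted p = 0.611), at mean levels of only 4.68 for Svs2 and 3.99 for Pbsn in DKO. Tested with an estimated correlation, all 8 lists had adjusted p = 0.285. Krt15, a keratin of basal cells, differed by -2.07 ± 0.27 (block -0.35, adjusted p = 0.798).

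In all 14011 of 18784 genes were called between the arrays labelled DKO and WT, 8193 higher and 5818 lower, and 3319 did not overlap, where chance gives 0.00108%. The median of all genes was 0.20 higher in DKO, and 0.02 after centring, when 6715 were higher and 6868 lower. Quantile normalization gave 6999 genes, 3273 higher and 3726 lower, so the direction of the excess flipped with either scaling. The number block gave 160 genes, 126 of them shared, with 70 higher and 90 lower. Within numbers 1 to 20 DKO is a single week 0 array, assumed to vary like the other groups, and 1889 genes were called against WT week 0. Krt1 then differed by 0.77 (adjusted p = 0.0488), Cyp1b1 by 2.38 (0.000435), Mc5r by -1.59 (0.00296) and S100a8 by 0.45 (0.401). Numbers 22 to 33 hold no WT array. Without the 9 low-range arrays DKO has 1 array at week 0 and 1 at week 12, and 7426 genes were called at these weeks with the spread of the other groups.

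At week 16 alone 7323 genes differed between the arrays labelled DKO and WT, 3910 higher and 3413 lower. Stfa1 was higher by 7.88 ± 0.64 log2 (adjusted p = 2.01e-07, block 9.64), Defb4 by 7.26 ± 0.60 (block 5.87), S100a8 by 7.34 ± 0.89 (adjusted p = 4.26e-05, block 6.12), Krt1 by 6.55 ± 0.49 (block 5.87) and Saa3 by 5.40 ± 0.60 (block 4.11). These 5 genes kept their calls with the block, as did Cyp1b1 (3.37 ± 0.39, block 4.52). Awat2 (-3.80 ± 0.79, adjusted p = 0.00185; block -3.10, adjusted p = 0.210) and Fasn (-2.86 ± 0.45; block -1.98, adjusted p = 0.124) lost theirs, and Awat2 also without DKO week 16 replicate 1 (-1.92, adjusted p = 0.0569). The cornified-layer list had 10 of 20 higher, 10 adjusted over the list alone (median 1.21, camera adjusted p = 0.00425). The sebaceous list had 12 of 19 lower and 1 higher, 14 and 1 adjusted over the list alone (median -1.87, camera adjusted p = 1.76e-05). The neutrophil list had 7 of 19 higher, 7 adjusted over the list alone (median 1.02, camera adjusted p = 0.00437). Cell cycle genes had 12 of 30 lower, 14 adjusted over the list alone (camera adjusted p = 0.000855). Lymphocyte genes had 5 of 11 higher, 6 adjusted over the list alone (0.0305), and accessory gland genes had 5 of 7, 5 adjusted over the list alone (0.00610). Glutathione genes had 6 of 16 lower and 1 higher, 6 and 1 adjusted over the list alone (0.0404). With an estimated correlation these lists had adjusted p = 0.310, and 0.376 for glutathione. With the number block the cornified-layer (median 0.92), sebaceous (-1.25) and neutrophil (1.01) lists kept their calls, and the cell cycle (adjusted p = 0.145), lymphocyte (0.300), accessory gland (0.216) and glutathione (0.782) lists did not. The number block gave 74 genes, 58 of them shared, and quantile normalization 2737. The count was 3019 and 2898 without WT week 16 replicates 1 and 2, and 3581 without DKO week 16 replicate 1. Within the other weeks 732 genes were called at week 0, 6925 at week 4, 5502 at week 8 and 1942 at week 12.

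Against Cyp1a1 KO, too, most cornified-layer and neutrophil genes measured were higher and most sebaceous genes lower in the arrays labelled DKO. The 3 lists passed with the preset correlation only (adjusted p = 0.267, 0.317 and 0.309 with an estimated correlation). Over all 18784 genes 11229 were called, so list counts are to be read beside that share. Averaged over weeks, Krt1 was higher by 4.19 ± 0.22 log2 (adjusted p = 8.54e-11, 10 arrays each), Krt10 was higher by 2.64 ± 0.17, Cnfn by 1.95 ± 0.17, S100a8 by 4.00 ± 0.40 and Cxcl2 by 2.96 ± 0.29. With the number block Krt1 (3.65), Krt10 (2.99) and Cnfn (adjusted p = 0.0414) kept their calls, and S100a8 (3.03, adjusted p = 0.146) and Cxcl2 (2.31, adjusted p = 0.112) did not. Plin2 (-1.73 ± 0.26), Pparg, a regulator of fat and sebaceous differentiation (-1.50 ± 0.24), Gclm, a partner of Gclc (-1.63 ± 0.23), Rrm2 (-1.08 ± 0.16) and Mdm2, the p53 ubiquitin ligase (-1.08 ± 0.19), were lower. None of these 5 was called with the block (Plin2 -1.13, Pparg -0.58, Gclm -0.02, Rrm2 -0.70), and Mdm2 turned to 0.09. The cornified-layer list had 15 of 20 higher, 15 adjusted over the list alone (median 0.89, camera adjusted p = 1.66e-05). The sebaceous list had 15 of 19 lower and 1 higher, the same adjusted over the list alone (median -0.95, camera adjusted p = 5.08e-05). The neutrophil list had 12 of 19 higher and 1 lower, 12 and 2 adjusted over the list alone (median 0.78, camera adjusted p = 0.00502). Cell cycle genes had 14 of 30 lower, 14 adjusted over the list alone (median -0.41, camera adjusted p = 0.00163). Lymphocyte genes had 8 of 11 higher, 9 adjusted over the list alone, and accessory gland genes 6 of 7, 6 adjusted over the list alone (both camera adjusted p = 0.0183). After the correlation was estimated, the last 3 of these lists had adjusted p = 0.390, 0.317 and 0.390. With the block the first 3 kept their calls at the preset correlation (medians 0.79, -0.47 and 0.57), the cell cycle list turned to 0.03 (adjusted p = 0.852), and the lymphocyte (0.479) and accessory gland (0.958) lists lost theirs.

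This comparison called 11229 genes, 6391 higher and 4838 lower, and 20 did not overlap, where chance gives 0.00108%. Centring turned the excess to 4915 higher and 5686 lower, and quantile normalization gave 2179 higher and 2769 lower of 4948. The number block gave 41 genes, 22 of them shared. Within numbers 22 to 33, where both genotypes have an array at week 12 only, 8 genes were called, with Krt1 at 5.76 (adjusted p = 0.00754) and Krt10 at 4.08 (0.0199). Within numbers 1 to 20, at week 0 only and with 1 DKO array, 4 genes were called, and Krt1 differed by 0.10 (adjusted p = 0.939). Without the 9 low-range arrays, with 1 DKO array at week 0 and 1 at week 12, the count was 1852.

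At week 16 alone 4041 genes differed between the arrays labelled DKO and Cyp1a1 KO, 1825 higher and 2216 lower. Krt1 was higher by 6.29 ± 0.49 log2 (adjusted p = 2.64e-07, block 5.61), S100a8 by 6.56 ± 0.89 (block 5.35, adjusted p = 0.0740), Defb4 by 5.46 ± 0.60 (block 4.07), Saa3 by 4.95 ± 0.60 (block 3.66) and Cxcl2 by 4.78 ± 0.64 (block 3.97, adjusted p = 0.0679). Awat2 was lower (-3.56 ± 0.79, adjusted p = 0.00635; block -2.86, adjusted p = 0.319), and Cyp1b1 was higher (1.33 ± 0.39, adjusted p = 0.0213; block 2.48). Awat2 lost its call without KO week 16 replicate 1 (adjusted p = 0.0565), KO week 16 replicate 2 (0.0539) or DKO week 16 replicate 1 (-1.68, 0.135). Cyp1b1 lost its call without KO week 16 replicate 1 (0.0765), KO week 16 replicate 2 (0.145) or DKO week 16 replicate 2 (0.87, 0.154). The sebaceous list had 6 of 19 lower, 9 adjusted over the list alone (median -1.26, camera adjusted p = 0.00103; block adjusted p = 0.103). The neutrophil list had 6 of 19 higher, 9 adjusted over the list alone (median 0.59, camera adjusted p = 0.00163). The cornified-layer list had 6 of 20 higher and 1 lower, 7 and 2 adjusted over the list alone (median 0.64, camera adjusted p = 0.00289). Interferon genes had 4 of 10 higher, 5 adjusted over the list alone (0.0454), stroma 3 of 14, 3 adjusted over the list alone (0.0497), accessory gland 4 of 7, 4 adjusted over the list alone (0.0264), and lymphocyte 1 of 11, 1 adjusted over the list alone (0.0497). Cell cycle genes had 6 of 30 lower, 6 adjusted over the list alone (0.0381; block median 0.11, adjusted p = 0.556). Tested with an estimated correlation, these 8 lists had adjusted p = 0.315, 0.315, 0.315, 0.315, 0.537, 0.370, 0.370 and 0.537. With the block the neutrophil, cornified-layer, interferon and stroma lists kept their calls, and the lymphocyte and accessory gland lists (both adjusted p = 0.817) did not. The count was 30 with the number block, 17 of them shared, 397 and 574 without KO week 16 replicates 1 and 2, and 913 without DKO week 16 replicate 1. Single weeks gave 0 genes by limma at week 0 (1601 at an unadjusted p under 0.05), 6360 at week 4, 4889 at week 8 and 81 at week 12.

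The changes from week 0 to week 16 were compared directly between genotypes. The change was more positive in the arrays labelled DKO than in WT for Stfa1 (8.15 ± 0.90 log2, adjusted p = 0.000148, 4 arrays each). It was so too for Defb4 (7.13 ± 0.84, adjusted p = 0.000230) and Krt1 (5.33 ± 0.70, adjusted p = 0.000849). Rnase2b, a ribonuclease of the eosinophil family (4.38 ± 0.74, adjusted p = 0.0235), and Stfa3 (3.56 ± 0.58, adjusted p = 0.0169) differed likewise. Cd300ld3, a leukocyte receptor, differed in the other direction (-4.69 ± 0.85, adjusted p = 0.0482). These were the 6 genes called. In WT itself the changes were -0.88 for Stfa1, -0.42 for Defb4, 0.32 for Krt1, -1.57 for Rnase2b, -0.46 for Stfa3 and 0.61 for Cd300ld3. Rnase2b rose by 2.81 in DKO. Against Cyp1a1 KO 3 genes were called, Krt1 (5.74 ± 0.70, adjusted p = 0.000762), Defb4 (5.57 ± 0.84, adjusted p = 0.0118) and Krt10 (3.41 ± 0.55, adjusted p = 0.0202). With the number block the same genes were called, within 21 and 31 genes. With only the groups compared in the fit 0 were called in either by limma, and with array weights 2 and 1, while quantile normalization raised both counts. Cd300ld3 also lost its call with median centring (adjusted p = 0.0517) and the replicate block (0.0741). The first count was 3 without WT week 16 replicate 1, 20 without DKO week 0 replicate 1 and 271 without DKO week 16 replicate 2. Rnase2b, Stfa3 and Cd300ld3 lost their calls in 5, 5 and 7 of the 8 fits that left out an array, with adjusted p up to 0.278, 0.264 and 0.311. The second count was 1 without KO week 0 replicate 1 or KO week 16 replicate 1, 6 without KO week 0 replicate 2, 14 and 125 without DKO week 0 replicates 1 and 2, and 399 without DKO week 16 replicate 2. Defb4 and Krt10 lost their calls in 3 and 5 of those 8 fits, with adjusted p up to 0.146 and 0.157.

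As a list, cornified-layer genes lay higher in the difference of DKO from WT (1 of 20 called, 3 adjusted over the list alone, median 0.85, camera adjusted p = 2.24e-05) and in that from Cyp1a1 KO (2 of 20, 4 adjusted over the list alone, median 0.78, camera adjusted p = 0.00111). Neutrophil genes did so too, with none called over all genes and 6 and 5 adjusted over the list alone (camera adjusted p = 0.000115 and 8.42e-05). Sebaceous genes lay lower in both (camera adjusted p = 0.00815 and 0.00490) with none called or adjusted over the list alone. With an estimated correlation these lists had adjusted p = 0.143, 0.291, 0.151, 0.177, 0.502 and 0.418. AhR targets lay higher as a list in the difference of DKO from WT, with 0 of 10 called (median 1.01, 3 adjusted over the list alone, camera adjusted p = 0.00148, and adjusted p = 0.143 with an estimated correlation). Against Cyp1a1 KO, macrophage (1 adjusted over the list alone, 0.00490), interferon (0 adjusted over the list alone, 0.00884) and stroma genes (1 adjusted over the list alone, 0.0306) lay higher, with adjusted p = 0.494, 0.177 and 0.499 with an estimated correlation. In both differences the sebaceous list lost its call with the number block (adjusted p = 0.278 and 0.192), and the other lists above kept theirs. Between Cyp1a1 KO and WT limma called 0 genes (61 at an unadjusted p under 0.05), and Cyp1b1 differed by 1.72 ± 0.55 (adjusted p = 1). AhR targets lay higher (median 0.30, 1 adjusted over the list alone, camera adjusted p = 0.0177) and stroma genes lower in that difference (median -0.52, 0 adjusted over the list alone, camera adjusted p = 0.00155), with adjusted p = 0.328 and 0.611 with an estimated correlation.

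The lists of p53 and DNA damage, invasion proteases, endothelium and red cells passed in none of the 15 comparisons. The nearest were p53 genes (DKO against WT, 4 of 20 higher and 11 lower, median -0.63, camera adjusted p = 0.0642), invasion proteases (WT over weeks 4 to 16, 0 of 9 called, median 0.23, camera adjusted p = 0.0741) and endothelium (Cyp1a1 KO against WT at week 16, 0 of 6 called, median -0.31, camera adjusted p = 0.0933). Between the arrays labelled DKO and WT, 4 of 6 endothelial genes were lower and 1 higher, without the list passing (median -0.72, camera adjusted p = 0.119). The red cell list, with 2 measured members, was nearest in DKO over weeks 4 to 16 (0 called, median 0.75, camera adjusted p = 0.406).

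**Figure D3:**
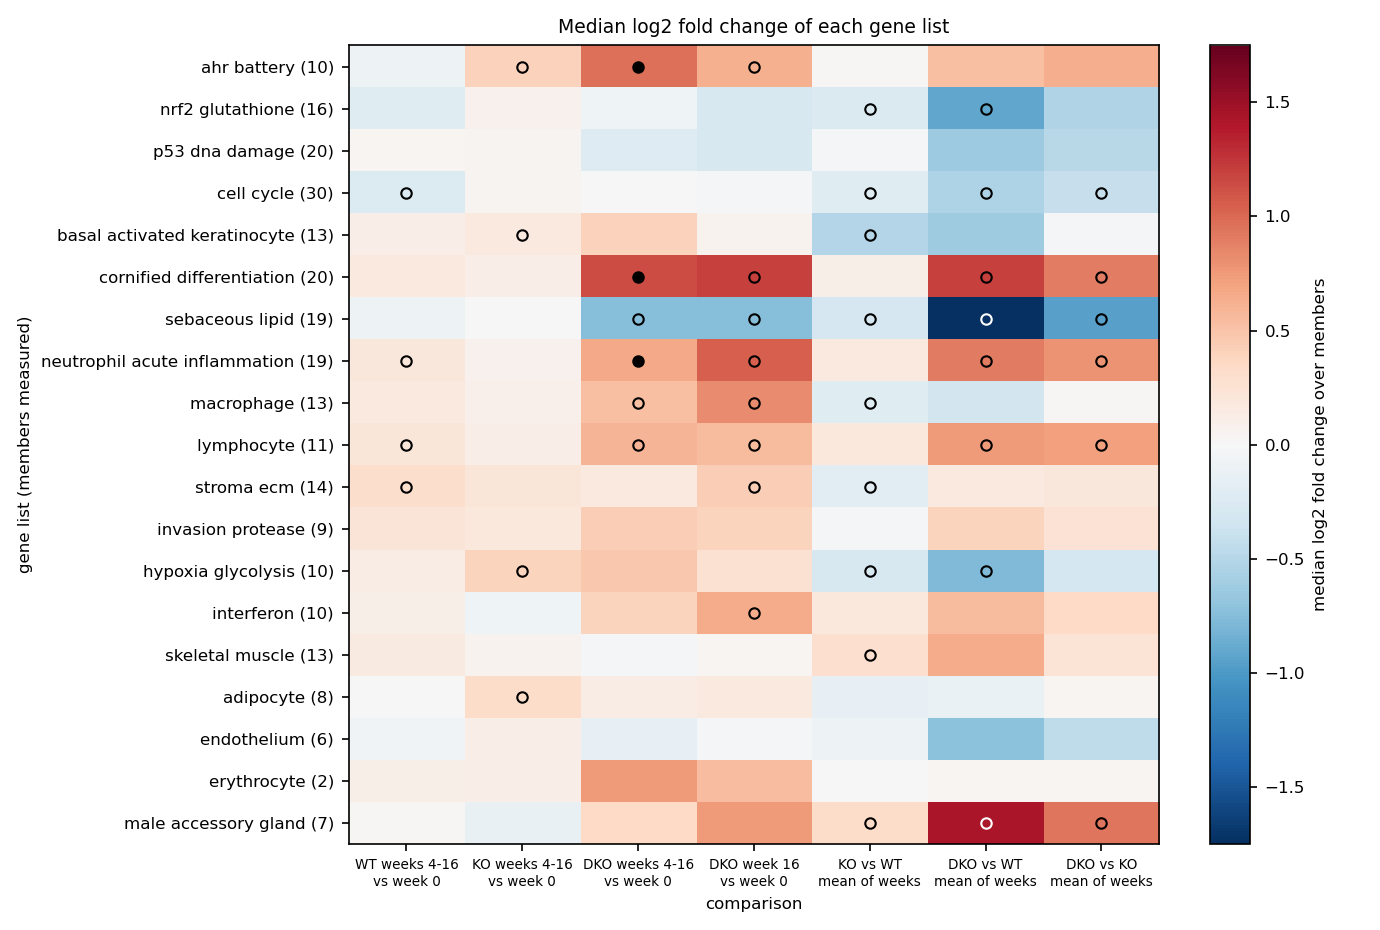
Median log2 difference of the members of each gene list (rows) in the comparisons named on the columns, as colour. A comparison without a column was tested but not drawn. An open circle marks a camera adjusted p under 0.05 with the preset correlation, and a filled circle one that held with the estimated correlation. The filled circles lie on the AhR, cornified-layer and neutrophil lists of DKO over weeks 4 to 16, with medians 0.97, 1.14 and 0.67.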

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

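Of the tests below, those of value range and swapped labels for Cyp1b1, that of value range for the cornified-layer and neutrophil genes, and the number block were chosen only after the results were seen. By a direct test of the difference, the change from week 0 to week 16 differed between the arrays labelled DKO and WT for 6 genes, with log2 differences of 8.15 for Stfa1, 7.13 for Defb4, 5.33 for Krt1, 4.38 for Rnase2b, 3.56 for Stfa3 and -4.69 for Cd300ld3. Against Cyp1a1 KO it differed for 3 genes, Krt1 (5.74), Defb4 (5.57) and Krt10 (3.41). With only the groups compared in the fit, none of these genes was called in either test. Several also lost their calls when single arrays were left out, as given above.

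The first pattern is that 14011 genes differed between the arrays labelled DKO and WT. In the pairs of arrays that differ in both value range and number range, Cyp1a1 KO week 12 and DKO week 0, the low-range array differed from its partner in the sign of the DKO minus WT difference of weeks 4, 8 and 16 in 92.8% of these genes (89.3% and 86.9% in each pair, and 76.3% in the DKO week 12 pair, which differs in value range alone and was not part of the test). Across genes, which are not independent replicates, r was 0.83 (0.52 in the DKO week 12 pair), and for the 25% of genes at the lowest and at the highest level the median differences were 1.05 and -1.02 for DKO minus WT against 1.03 and -1.08 within the pairs. A narrow value range of the arrays, which also reaches a Cyp1a1 KO array, may therefore account for most of these genes. In 100 splits within weeks, 1 of them the real one, the real split gave the most genes. The highest other split gave 10589 genes (10897 against 11229 for DKO and Cyp1a1 KO), which points to a structure of the samples. The real split also follows value range and label number, so its rank cannot tell genotype from these. Genotype stays open beside the value range, since genotype and range were nearly the same split.

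The second pattern is that Cyp1b1 was higher in the arrays labelled DKO, where the gene was targeted, than in the other genotypes. The value range argues the other way, since the low-range array differed from its partner by a mean of -1.15 log2 in the same 2 pairs (-1.04 and -1.26), and by -0.24 in the DKO week 12 pair. A swap of part of the labels of Cyp1a1 KO and DKO at weeks 4 to 16 is argued against because the lowest of 8 DKO arrays (9.48) lay 0.65 above the highest of 8 Cyp1a1 KO arrays (8.82), while an exchange of all of them would leave the same gap and stays open. A probe set outside the deleted part, transcribed from an allele that makes no enzyme, stays open as a candidate explanation, as does DKO material that differs from its label as a whole; neither was tested.

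The third pattern is the rise of cornified-layer and neutrophil genes in the arrays labelled DKO. Normal skin dissected with the gland is argued against as the main source. The 17 measured of 19 markers of normal epidermis and hair follicle changed by a median of 0.30 at weeks 8 to 16. Of these, 0 rose by 2 or more (highest 1.92), while Krt1 changed by 5.57. Most of the markers are hair follicle genes. Those of epidermis all rose, by 0.42 (Krt2), 0.32 (Krt77), 0.73 (Flg2), 1.92 (Hrnr) and 0.45 (Lor, also in the cornified-layer list). A smaller admixture of epidermis stays open. The value range stays open for a part of the rise, since over all 39 members the mean difference of the low-range arrays in the same 2 pairs had a median of 0.31 log2 (0.15 for cornified-layer and 0.62 for neutrophil genes) and the DKO change at week 16 one of 1.06. Against it, the DKO week 12 pair gave -0.14, and the single normal-range DKO array of week 12 lay 1.62 above that of week 0 (1.70 and 1.03 by list). That week 12 array had the narrowest range of the 21 normal-range arrays (SD 1.70). Its pair may therefore show less of a range effect, here and above. With the number block both lists kept their calls at week 16 with the preset correlation (medians 0.88 and 0.91), but without the block neither passed with an estimated correlation (each adjusted p = 0.107). An effect of age shared by the genotypes is argued against for Krt1, whose change differed directly from WT (5.33) and Cyp1a1 KO (5.74). Neither of these differences was called with only the groups compared in the fit. Ageing particular to DKO, BaP and squamous change in the gland stay open.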

How the results depend on the processing

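The number block, the fits within number ranges and the fit without the 9 low-range arrays were tests chosen only after the results were seen, and the others were planned; the cause was not tested where a count moved. Counts of called genes are compared with 0 in the WT and Cyp1a1 KO changes, 183 and 759 in DKO (weeks 4 to 16, week 16), 813, 14011 and 11229 (means over weeks: KO-WT, DKO-WT, DKO-KO), 12, 7323 and 4041 (week 16) and 0, 6 and 3 (difference tests). Quantile normalization moved 11 of 15: 1 (KO weeks 4 to 16) and 1 (KO week 16), 413 and 1630 (DKO), 128, 6999 and 4948 (means), 2737 (DKO-WT week 16), 1947 (DKO-KO week 16), and 53 and 85 (DKO difference tests). The filter and the trend with robust variances moved the DKO-KO difference test alone, to 10 and 8; median centring and the mean of probe sets moved none. Array weights moved 9: 1 and 3 (KO), 2 and 5 (DKO), 11 (WT week 16), 3745 (KO-WT mean), 4592 (KO-WT week 16), and 2 and 1 (DKO difference tests). With only the groups compared 7 moved: 9 and 5 (DKO), 3325 (KO-WT mean), 3707 (KO-WT week 16), 1934 (DKO-KO week 16), and 0 and 0 (DKO difference tests, limma). The number block moved 10: 1 and 1 (KO), 606 (DKO weeks 4 to 16), 160 (DKO-WT mean), 41 (DKO-KO mean), 64, 74 and 30 (week 16), and 21 and 31 (DKO difference tests). Without the 9 low-range arrays 7 moved: 3 and 11 (KO), 1482 (DKO weeks 4 to 16), 4876, 7426 and 1852 (means) and 2743 (KO-WT week 16); DKO then had 1 array at week 0 and 1 at week 12, so its values are for those weeks, with the spread of other groups. Within numbers 1 to 20, 6 moved: 3 and 11 (KO), 4876, 1889 and 4 (means) and 2743 (KO-WT week 16); within 22 to 33, 3 moved: 12 and 8 (DKO) and 8 (DKO-KO mean).

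Taking the replicate numbers of the labels as a pair block moved 1 of 15 counts, KO-WT at week 16, to 7. Of 105 pairs of groups, the correlation of residuals ran from -0.55 to 0.67 with a median of -0.02, and 16 lay above 0.1, so no general pairing by number was seen. Leaving out 1 array gave 0 to 1 genes (KO weeks 4 to 16), 143 to 1508 and 194 to 3393 (DKO), 449 to 3248, 13405 to 14453 and 9857 to 12353 (means), 2 to 3, 2898 to 6802 and 397 to 4399 (week 16), and 3 to 271 and 1 to 399 (DKO difference tests); a lone array was assumed to vary like the other groups. Values that changed sign were Cyp1b1 in WT over weeks 4 to 16 without WT week 0 replicate 2 (-0.00159, highest 0.31 without WT week 0 replicate 1), the DKO-KO cell cycle list with the number block (0.034, and 0.11 at week 16), Mdm2 in DKO-KO with the block (0.088), within 1 to 20 (0.19) and within 22 to 33 (0.34), and Gclm there (0.037). Of 80 list results, 56 kept direction and call with the number block, 60 with quantile normalization, 79 with centring, 80 with the pair block and 3 with an estimated correlation. Of 116 named gene results, 86 kept both with the block, 86 with array weights, 100 with quantile normalization, 82 with only the groups compared and 112 with centring. The low-value filter left 3 of them out, and the 3 fits on part of the arrays gave no value where a group had no array. Single-week counts, 2 (WT week 12) and 1 (KO week 4), moved to 0 and 0 with quantile normalization and with only the groups compared, and to 4 and 23 within numbers 1 to 20 and without the low-range arrays. Array weights gave 5 and the number block 3 in KO week 4. Simulated genes with a true log2 change of 1 were recovered in 1.49% in the KO-WT difference test and 79.1% in the KO-WT mean.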

Other observations

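The tests of flanking genes and of splits within weeks below were planned before their results were seen. The other values were chosen after the results were seen. The rise in the arrays labelled DKO lay between different weeks for different genes. Mean Stfa1 was 4.64, 8.17, 11.78, 12.02 and 11.90 at weeks 0, 4, 8, 12 and 16, and Defb4, the beta-defensin, was 3.80, 7.41, 10.13, 10.76 and 10.51. Krt1 was 4.92 and 5.92 at weeks 0 and 4 and 10.37 at week 8. S100a8 was 4.23 and 4.53 at weeks 0 and 4, and at week 8 its 2 arrays lay at 6.90 and 11.53. Awat2, the wax ester synthase, was 10.12, 9.39, 8.27, 8.88 and 6.92. The order of these genes in time was not tested. In Cyp1a1 KO, mean Stfa1 was 7.15 at week 0 and 9.89 at week 16.

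Between Cyp1a1 KO and WT 813 genes were called. Of 100 splits within weeks, 1 of them the real one, the highest other gave 1 gene. Label numbers also followed genotype here, so the splits cannot tell genotype from the order of the numbers. A candidate explanation for a part of the 813 genes is DNA of the donor strain around the targeted Cyp1a1 gene. Of 811 called genes with a known position, 21 (2.59%) lay within 20 Mb of Cyp1a1, against 460 of 18774 tested (2.45%), with a one-sided Fisher exact p = 0.429. The share among called genes was about that among all genes, so this test leaves the explanation open for single genes such as Hspa8, which lies in that region.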
